A study of Mus musculus with 4 samples.

How the data were processed

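Retinal RNA of 3-week-old mice was measured by RNA sequencing in 4 libraries, 2 from wild-type mice (WT) and 2 from mice with the mutation Q344X, known from autosomal dominant retinitis pigmentosa, an inherited loss of photoreceptors. Per the labels' protocols, retinas were placed in a stabilization reagent, total RNA was purified on columns (RNeasy), polyadenylated RNA was selected, directional libraries were made with a NEBNext kit and sequencing was on an Illumina HiSeq instrument. The series' design text states that the study began with 3 replicates per group and kept 2 animals per group after low-quality RNA and outlying samples were removed, whereas the extraction protocol names 3 Q344X and 2 WT mice. The rule by which samples were removed is not given in the sources used here, and the labels do not say how the allele was made, whether the mice carried 1 or 2 copies, or the sex and litter of the animals.

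The deposited table holds a signal per gene that the authors made by dividing gene counts by a size factor for each library, in 52636 Ensembl genes. Per the submitters' processing notes, the tools named were FastQC, Trim Galore 0.4.4, STAR, featureCounts and DESeq2 1.16.1, with the genome build mm10; the notes give no roles, and the gene annotation and the strand setting of the counting are not given in the sources used here. Every deposited value above 0 was a whole multiple of the worth of 1 read in its column, with 100% of the values within 0.1 of a whole number. The depth computed from this was 18452679 and 19706573 reads in genes for WT replicates 1 and 2, and 19034261 and 19346580 for Q344X replicates 1 and 2, with size factors of 0.962, 0.997, 1.01 and 1.04. For WT replicate 2 and Q344X replicate 1, where 1 read is worth close to 1, these reads did not pass a unit check. The tests were run on the normalized values, and no count model was fitted.

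Symbols were paired by Ensembl identifier for 52403 of the 52636 genes, 233 had no match, and 21820 were at 0 in every library. Positions, gene types and lengths are those of GENCODE release M21 on GRCm38, the assembly also known as mm10. Genes with a mean normalized count of at least 10 over the 4 libraries were tested, which left 16833. The main test, in R 4.3.3 with limma 3.58.1, was a linear model of log2(normalized count + 1) on genotype with moderated variances and a mean-variance trend (2 residual and 3.90 prior degrees of freedom), Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. All tests were two-sided. A permutation test of 1 gene in 2 against 2 libraries cannot give a p below 0.333, so the adjusted p-values rest on the variance that limma shares between genes. Values per group are means with the SD over n = 2 libraries, and p-values measure the spread between these libraries, which the data do not show to be 1 animal each.

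Gene lists for 34 pathways and cell types (648 entries, 1 without a match in the table) were fixed before the data were examined, and so were the tests, the filter, most of the alternatives and the rule for the genes named in the text. The rule took, among others, the 14 genes with the largest rise and the 14 with the largest fall among those past the threshold with a mean of at least 50 and no overlap between the groups. Gene models, pseudogenes and clone names were skipped, 8 among the rising and 18 among the falling genes. In each list up to 4 members were named, those past the threshold with the largest change first and then those with the highest mean; members named beyond these were chosen after their values were seen. Some genes picked by the rule are not reported here. Lists with at least 5 tested members (33 of the 34, all but skeletal muscle) were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. The same test with an estimated correlation and limma's fry, which asks whether the members move on balance one way, were the alternatives. With an estimated correlation, camera's test has only the 2 residual degrees of freedom, so few lists could pass it and a failure decides little. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Other alternatives were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50, scaling to the 75th percentile, quantile normalization, robust variance moderation, a minimum log2 change of 1 and leaving out each library in turn. A fit without 1 library takes its residual variance from the intact pair alone, so its calls also depend on the spread of that pair. A correction of each library for gene length and GC content by a loess fit was added after the data were seen. Length was the union of a gene's annotated exons, and GC content was that of its longest annotated transcript.

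The gene test was tested on simulated data for the comparison of Q344X with WT, made from the real gene means and size factors with 200 changed genes. At a dispersion of 0.0278, the level matching the median spread within groups, 61.6% of genes changed 2-fold and 98.9% of genes changed 4-fold were recovered among 16664 genes, with 9 false calls. At a larger dispersion of 0.0430 the shares were 25.5% and 96.9% among 16657 genes, with 5 false calls. Each simulation gave all genes the same dispersion and drew them independently, whereas real genes differ in spread and vary together between libraries. It also changed only 200 genes, against 2450 called in the real data, and this number affects the adjusted p-values. The recovered shares and false calls may therefore not hold for the real data. In these simulations camera called the shifted list and 0 of 33 unchanged lists, but genes were drawn independently, so this does not test the preset correlation, and estimated correlations reached 0.801 in the ribosomal protein list and 0.983 in the lens list. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.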

Results

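Gene expression in the retina was compared between 3-week-old WT mice and mice with the mutation Q344X, which is known from autosomal dominant retinitis pigmentosa, an inherited loss of photoreceptors, with 2 libraries per group. The question was which genes differ in expression in the mutant retina. Reads in genes, as recovered from the normalized values, came to 18452679 and 19706573 in WT replicates 1 and 2. They came to 19034261 and 19346580 in Q344X replicates 1 and 2. In the same order, 25100, 24683, 25405 and 26146 genes were above 0. Across the tested genes, log2 values correlated with r = 0.982 between the WT libraries, 0.973 between the Q344X libraries and 0.907 to 0.935 between libraries of different genotype (correlations across genes, which are not independent replicates). The first principal component held 74.8% of the variance and separated the genotypes, and the second held 18.9% and separated the libraries within each genotype.

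In the Q344X retina, 919 genes were higher and 1531 were lower than in WT among 16833 tested (limma, adjusted p under 0.05). Of these, 658 higher and 1274 lower genes changed by at least 1 on the log2 scale. In all 2450 the libraries of the 2 genotypes did not overlap, as in 63.1% of all tested genes, where chance gives 33.3% for a single gene. Genes vary together between libraries, so this share is no test of genotype. The median log2 fold change over all tested genes was 0.02, and 0.05 under both 75th percentile scaling and quantile normalization. Without WT replicate 1 the counts were 555 and 904, without WT replicate 2 there were 575 higher genes, and without Q344X replicate 1 the counts were 2388 and 3045. Testing every gene above 0 gave 153 and 383 and ended the calls of 76 of the 118 called genes that the naming rule picked, Il20rb, Hist1h1e and Edn2 among them, and the length and GC correction gave 1766 higher genes.

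**Figure D1:**
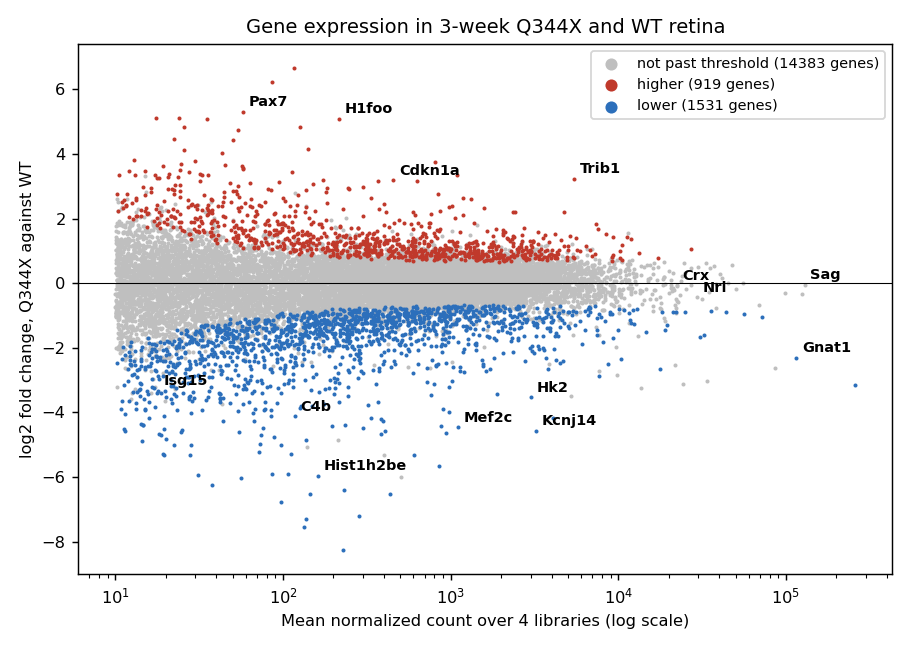
Log2 fold change of each tested gene in Q344X against WT retina (vertical axis) against its mean normalized count over the 4 libraries (horizontal axis, log scale). Red points are the 919 higher and blue points the 1531 lower genes. Gnat1, at -2.31, is lower among the abundant genes, while Sag, Crx and Nrl lie nearer to 0.

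The genes with the largest rise were mostly rare in WT retina. Pax7, a paired-box transcription factor of muscle satellite cells and neural crest (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528, GRCm38), rose from 2.02 ± 1.39 to 113 ± 13.5 normalized counts (SD, n = 2, log2 fold change 5.31 ± 0.47, SE). H1foo, the oocyte linker histone, rose from 11.2 ± 0.290 to 419 ± 41.8 (5.10 ± 0.25). Trib1, a pseudokinase, was the most abundant of this group and rose from 1040 ± 162 to 9839 ± 1926 (3.24 ± 0.22). Cdkn1a, which encodes the cell-cycle inhibitor p21, rose from 89.2 ± 7.08 to 822 ± 67.5 (3.19 ± 0.20). Among the others, log2 fold changes were 4.43 for Prss33 (a serine protease), 4.15 for Rilp (a lysosomal Rab effector), 3.74 for Kif19a (a kinesin), 3.63 for Wfikkn1, 3.56 for Ankrd2, 3.53 for Il20rb (a cytokine receptor subunit), 3.45 for Slc25a18 (a mitochondrial glutamate carrier), 3.34 for Ccdc187 and 3.07 for Ager (the receptor for advanced glycation end products). Adjusted p lay between 0.00274 for H1foo and 0.0126 for Il20rb (limma), and none of these genes lost its call when 1 library was left out.

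Larger changes were seen among the genes that fell. Mef2c, a transcription factor expressed in photoreceptors (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080), fell from 2111 ± 9.07 to 97.3 ± 29.0 normalized counts (SD, n = 2, log2 fold change -4.46 ± 0.25, SE). Kcnj14, an inward-rectifier potassium channel gene, was the most abundant and fell from 6204 ± 1406 to 264 ± 77.6 (-4.56 ± 0.28). Edn2, encoding endothelin 2, was at 289 and 58.2 in the WT libraries and at 4.95 and 2.88 in the Q344X libraries (-4.77 ± 0.77). The histone genes Hist1h2be, Hist1h1e and Hist1h2ac had log2 fold changes of -5.96, -5.91 and -4.49, with Hist1h1e at 0 in Q344X replicate 2. Histone genes have near-identical copies, so reads may be split between them. The antisense genes Ube4bos1 and Pitpnm2os2 had -6.41 and -4.65, values that are uncertain because the strand setting of the counting is not given. The others were Slc26a4 (the anion exchanger pendrin) at -5.22, Sh2d1a at -4.86, Ahrr (the aryl hydrocarbon receptor repressor) at -4.66, Traf3ip3 at -4.48, Chst3 (a chondroitin sulfotransferase) at -4.42 and Col6a3 (a collagen chain) at -4.38. Adjusted p lay between 0.00274 for Ube4bos1 and 0.0186 for Edn2 (limma), and none of the 14 lost its call when 1 library was left out.

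Genes of rod phototransduction fell as a group and unevenly. Of 22 members, 11 fell, 0 rose and 11 did not pass. Adjusted over the list alone, 16 fell and 0 rose. The median log2 fold change was -1.12 (fry adjusted p = 0.0323, camera adjusted p = 1.2e-06, and adjusted p = 0.584 with an estimated correlation). Leaving out 1 library gave medians of -1.32 to -0.91, and 1 member rose under quantile normalization. Among those that fell were Guca1b (-2.67 ± 0.24, SE) and Guca1a (-2.50 ± 0.24), which encode guanylate cyclase activators, and Gnat1 (-2.31 ± 0.20), the rod transducin alpha subunit, whose mean fell from 191900 ± 17428 to 38699 ± 1460 normalized counts (SD, n = 2). Pde6a (-1.68) and Grk1 (-1.60) also fell, whereas Sag, which encodes rod arrestin, had -0.04 ± 0.20, Cnga1 -0.04 ± 0.22 and Pdc 0.57 ± 0.23, none past the threshold.

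Genes of rod identity and of the outer segment moved in different directions. Of 21 tested members, Samd7 (1.44 ± 0.23, SE) and Samd11 (0.93 ± 0.19), photoreceptor repressor proteins, rose, 4 fell and 15 did not pass. With p adjusted over the list alone, 3 rose and 5 fell (median -0.38, camera adjusted p = 0.151). Those that fell were Fscn2 (-1.88), Pcdh15 (-1.64), Impg1 (-1.38) and Rp1l1 (-1.25). The transcription factors Nrl, Crx and Nr2e3 had log2 fold changes of -0.43 ± 0.28, -0.08 ± 0.18 and 0.51 ± 0.21, none past the threshold, and the structural genes Rom1 and Rp1 had -0.02 ± 0.29 and 0.01 ± 0.19. Samd11 did not pass without WT replicate 1 (adjusted p = 0.193) or 2 (0.0819), nor did Rp1l1 without WT replicate 2 (0.0599). Without WT replicate 1 camera gave adjusted p = 0.0365 for this list.

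Cone and synaptic genes of photoreceptors were also lower. Of 17 cone genes, 7 fell, 0 rose and 10 did not pass. In the counts adjusted over the list alone, 10 fell (median -0.84, fry adjusted p = 0.0323, camera adjusted p = 0.000367, and adjusted p = 0.584 with an estimated correlation). Pde6h (-2.59 ± 0.42, SE) and Arr3 (-2.17 ± 0.30), a cone phosphodiesterase subunit and cone arrestin, fell, as did Guca1a and Gucy2e (-1.69 ± 0.19), which are in the rod list too. The opsin gene Opn1sw fell by 1.05, and Opn1mw had -0.63, not past the threshold. Of 18 genes of the photoreceptor ribbon synapse, 6 fell, 0 rose and 12 did not pass. Adjusted over the list alone, 8 fell and 1 rose (median -0.69, fry adjusted p = 0.0498, camera adjusted p = 0.00436, and adjusted p = 0.584 with an estimated correlation). Cabp4 (-1.63 ± 0.23), a calcium sensor of the terminal, and Cplx4 (-1.45 ± 0.17), a complexin, fell most, followed by Pclo (-1.28) and Egflam (-1.20). Leaving out 1 library gave 4 to 8 cone genes and 3 to 10 synaptic genes that fell. Pclo had adjusted p = 0.0505 without WT replicate 1 and Egflam 0.0720 without WT replicate 2, and Opn1sw had 0.0693 and 0.0796 with WT replicate 1 or 2 left out.

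Genes of glycolysis, on which photoreceptors rely, were lower in part. Of 21 members 4 fell, 0 rose and 17 did not pass, with 4 lower adjusted over the list alone. The list median was -0.31 (fry adjusted p = 0.0239, camera adjusted p = 0.00107, and adjusted p = 0.584 with an estimated correlation). Hk2, a hexokinase, fell from 5521 ± 196 to 484 ± 108 normalized counts (SD, n = 2, log2 fold change -3.53 ± 0.21, SE), Slc16a3, a lactate transporter, fell by 1.81, Pfkl, a phosphofructokinase, by 1.37 and Hk1 by 0.82. Hk1 did not pass without WT replicate 1 (adjusted p = 0.0967), without WT replicate 2 (0.304) or under quantile normalization (0.0581). Of 17 visual cycle genes, Rdh10 (1.21) and Rpe65 (1.19) rose, Abca4 (-1.30), Retsat (-1.24), Rbp3 and Rdh11 fell and 11 did not pass. With p adjusted over the list alone, 3 rose and 5 fell (camera adjusted p = 0.950). Retsat, Rbp3 and Rdh11 did not pass without WT replicate 1 (adjusted p = 0.0601 to 0.145) or 2 (0.0848 to 0.184), nor did Rbp3 under quantile normalization (0.132) or Rpe65 without WT replicate 2 (0.0697). Of 36 ciliary trafficking genes, Tulp3 (0.97) rose, Ift80 (-1.43), Mak (-1.33), Arl13b (-0.81) and Bbs4 fell and 31 did not pass, with the same numbers adjusted over the list alone (median -0.22, camera adjusted p = 0.112). Tulp3, Arl13b and Bbs4 did not pass with either WT library left out (adjusted p = 0.104 to 0.284), and Mak did not without WT replicate 1 (0.0623).

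**Figure D2:**
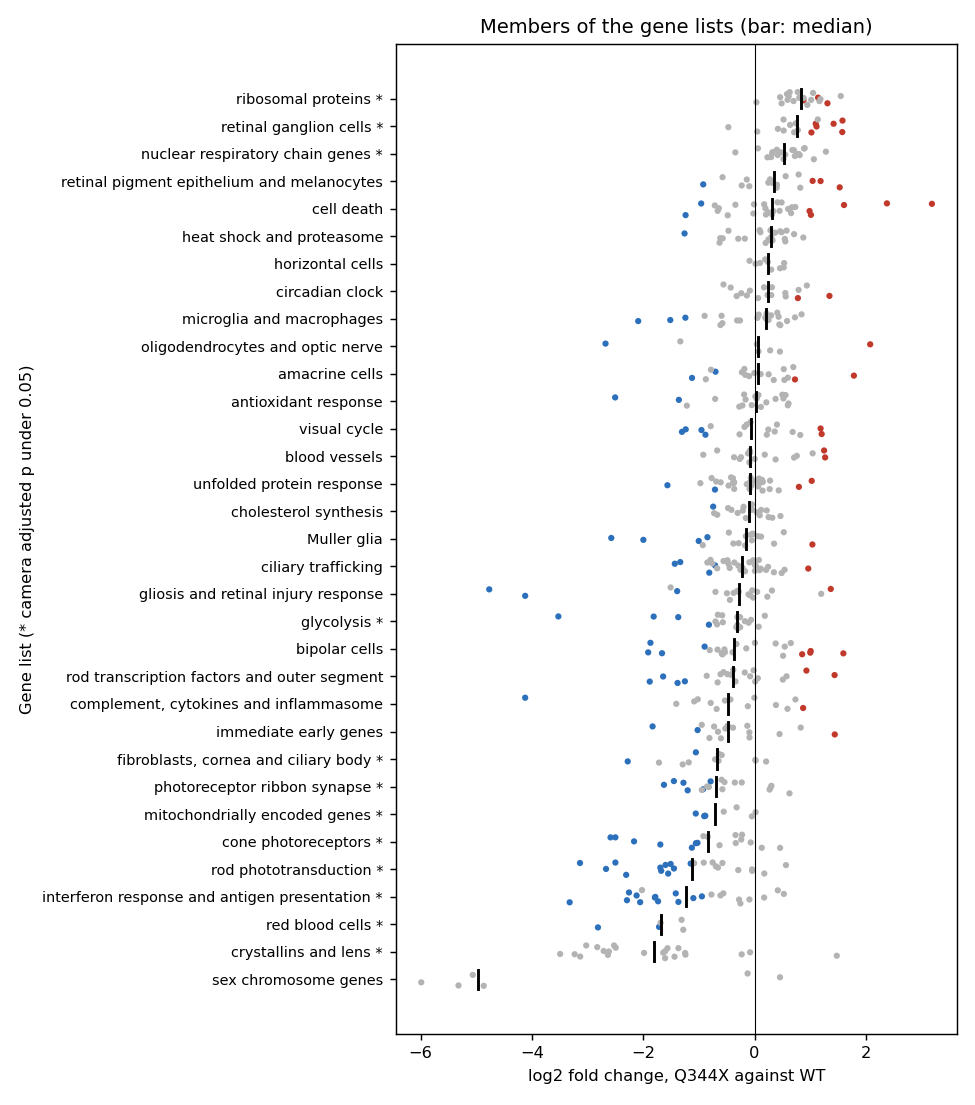
Log2 fold change in Q344X against WT retina of each tested member of the gene lists with at least 5 tested members (points; red higher and blue lower at adjusted p under 0.05, grey not past it; black bars, list medians). Asterisks mark the 12 lists past the camera threshold at the preset correlation. The rod phototransduction bar lies at -1.12 and the ribosomal protein bar at 0.84.

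Interferon response and antigen presentation genes were lower in Q344X. Of 22 tested members, 12 fell, 0 rose and 10 did not pass. In the counts adjusted over the list alone, 13 fell (median -1.23, fry adjusted p = 0.0239, camera adjusted p = 4.4e-05, and adjusted p = 0.584 with an estimated correlation). Isg15 (log2 fold change -3.32 ± 0.65, SE), Usp18 (-2.29 ± 0.41), Ifi27 (-2.26 ± 0.31) and Ifit1 (-2.12 ± 0.43) fell from low levels. Leaving out 1 library gave 7 to 13 members that fell, and Usp18 had adjusted p = 0.0646 without WT replicate 2. Of 14 tested complement, cytokine and inflammasome genes, C4b (complement component 4) fell, with -4.12 ± 0.56, Vcam1 rose, with 0.87 ± 0.20, and 12 did not pass. Adjusted over the list alone, 3 rose and 3 fell (median -0.48, camera adjusted p = 0.412). Vcam1 did not pass without WT replicate 1 (adjusted p = 0.112) or 2 (0.258).

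Glial and immune markers moved in both directions. Of 20 tested genes of gliosis and injury, Edn2, C4b and Ednrb (-1.39 ± 0.20, SE) fell, Lcn2 (lipocalin 2; 1.37 ± 0.28) rose and 16 did not pass, with 1 higher and 3 lower adjusted over the list alone (median -0.29, camera adjusted p = 0.158, or 0.0149 without WT replicate 2). Lcn2 had adjusted p = 0.118 without WT replicate 1. Gfap, the intermediate filament of reactive glia, was at 1047 ± 133 in WT and 840 ± 7.38 in Q344X (SD, n = 2, log2 fold change -0.31 ± 0.18), not past the threshold. Of 19 Müller glia genes, Car14 (1.04) rose, Spc25 (-2.58), Abca8a, Aqp4 and Kcnj10 fell and 14 did not pass. With p adjusted over the list alone, 1 rose and 5 fell (median -0.16, camera adjusted p = 0.155). Aqp4 and Kcnj10 did not pass without WT replicate 1 (adjusted p = 0.148 and 0.163) or 2 (0.0721 and 0.207), nor did Car14 without WT replicate 2 (0.143). Of 24 microglia and macrophage genes Cd74 (-2.09), Spp1 (-1.51) and Gpnmb (-1.24) fell, 0 rose and 21 did not pass, with 3 lower adjusted over the list alone. All 3 lost their calls without WT replicate 2 (adjusted p = 0.110, 0.0650 and 0.0698). The median of this list was 0.20 and its mean -0.11, with camera pointing up and fry down (camera adjusted p = 0.956).

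Retinal ganglion cell genes were higher in Q344X. Of 16 members, 6 rose, 0 fell and 10 did not pass. In the counts adjusted over the list alone, 12 rose (median 0.76, camera adjusted p = 3.1e-05, and adjusted p = 0.584 with an estimated correlation, fry adjusted p = 0.0652). Gap43, a growth cone protein, and Isl2, a transcription factor, had log2 fold changes of 1.58 ± 0.17 and 1.58 ± 0.32 (SE), Tubb3, a neuronal tubulin, 1.42 ± 0.17 and Sncg, gamma-synuclein, 1.11 ± 0.25. Leaving out 1 library gave 3 to 11 members that rose, and Sncg had adjusted p = 0.126 without WT replicate 1. Bipolar cell genes moved both ways. Of 22, 4 rose, the transcription factors Isl1, Lhx3 and Lhx4 among them, Nyx (-1.91 ± 0.26), Sebox (-1.87 ± 0.24), Tacr3 (-1.66 ± 0.18) and Lrit3 fell, and 14 did not pass. Adjusted over the list alone, 5 rose and 8 fell (camera adjusted p = 0.353). Lhx3, Lhx4 and Lrit3 lost their calls with either WT library left out (adjusted p = 0.102 to 0.229), and 1 bipolar gene rose and 3 fell in each of these fits. Of 18 amacrine cell genes, Neurod6 (1.79) and Ebf3 (0.73) rose, Slc17a8 (-1.12) and Slc6a9 (-0.70) fell and 14 did not pass, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.607). Each of these 4 lost its call without WT replicate 1 (adjusted p = 0.0795 to 0.310), and all but Neurod6 did without WT replicate 2 (0.0733 to 0.284). Of 9 tested horizontal cell genes none passed, also adjusted over the list alone (limma, median 0.24, camera adjusted p = 0.190), and Prox1, Tfap2b, Sept4 and Calb1 had log2 fold changes of 0.02, 0.53, 0.30 and -0.09.

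Ribosomal protein genes shifted upward together, although few passed singly. Of 20 members, 3 rose, 0 fell and 17 did not pass. With p adjusted over the list alone, 11 rose (median 0.84, camera adjusted p = 1.7e-05, and adjusted p = 0.604 with an estimated correlation, fry adjusted p = 0.216). Rpl5 (1.31 ± 0.19, SE), Rplp0 (1.14 ± 0.28) and Rps24 (0.88 ± 0.22) rose, and Rpl4 had 0.70 ± 0.19. Leaving out 1 library gave between 1 member that rose (without WT replicate 1) and 19 (without Q344X replicate 1). Rplp0 and Rps24 lost their calls without WT replicate 1 (adjusted p = 0.118 and 0.213) and under quantile normalization (0.0608 and 0.0662), and Rps24 also without WT replicate 2 (0.122) or Q344X replicate 2 (0.0576). The median of this list differed by 0.67 between the Q344X libraries, replicate 2 minus replicate 1, and by 0.38 between the WT libraries.

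The nuclear genes of the respiratory chain had a median of 0.54, with 0 of 20 members past the threshold in limma, also adjusted over the list alone (camera adjusted p = 0.000871, and adjusted p = 0.604 with an estimated correlation, fry adjusted p = 0.270). Atp5b, Atp5a1, Cox4i1 and Sdha had 0.23, 0.55, 1.07 and -0.35. Without Q344X replicate 1, 13 of the 20 rose. The median of this list also differed between replicates 2 and 1, by 0.49 in Q344X and 0.28 in WT. Genes encoded in the mitochondrial genome went the other way. Of 8 tested, mt-Cytb (-1.06 ± 0.21, SE), mt-Nd5 (-0.90), mt-Nd2 (-0.90) and mt-Nd4 (-0.88) fell and 4 did not pass, with 5 lower adjusted over the list alone (median -0.72, camera adjusted p = 0.0188, and adjusted p = 0.604 with an estimated correlation, fry adjusted p = 0.0732). None of these 4 passed without WT replicate 1 (adjusted p = 0.108 to 0.290), without WT replicate 2 (0.0566 to 0.124) or under quantile normalization (0.103 to 0.362). Camera gave this list adjusted p = 0.312 under quantile normalization, 0.123 without WT replicate 1, 0.0827 without Q344X replicate 1, 0.0564 without Q344X replicate 2 and 0.0654 with the length and GC correction.

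Cell death genes included several that rose. Of 27 tested, 5 rose, 2 fell and 20 did not pass. In the counts adjusted over the list alone, 6 rose and 2 fell (median 0.32, camera adjusted p = 0.103, fry adjusted p = 0.0498). Cdkn1a, Bbc3 (2.38 ± 0.52, SE), Bid (1.01 ± 0.25) and Bax (0.99 ± 0.21), targets of p53 or members of the BCL2 family, were among those that rose, and Bcl2 (-0.96 ± 0.23) was among those that fell. Bid, Bax and Bcl2 lost their calls with either WT library left out (adjusted p = 0.0920 to 0.251), Bid also without Q344X replicate 2 (0.0891) and Bcl2 under quantile normalization (0.0688). Of 31 unfolded protein response genes, Selenos (1.03) and Asns (0.80) rose, Atf3 (-1.57) and Pdia6 (-0.71) fell and 27 did not pass, and adjusted over the list alone 0 passed (limma, median -0.09, camera adjusted p = 0.353). Hspa5 and Ddit3, which encode BiP and CHOP, had -0.14 ± 0.17 and -0.37 ± 0.25. Selenos, Asns, Atf3 and Pdia6 lost their calls without WT replicate 2 (adjusted p = 0.0653 to 0.266), and all but Atf3 did without WT replicate 1 (0.160 to 0.306).

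**Figure D3:**
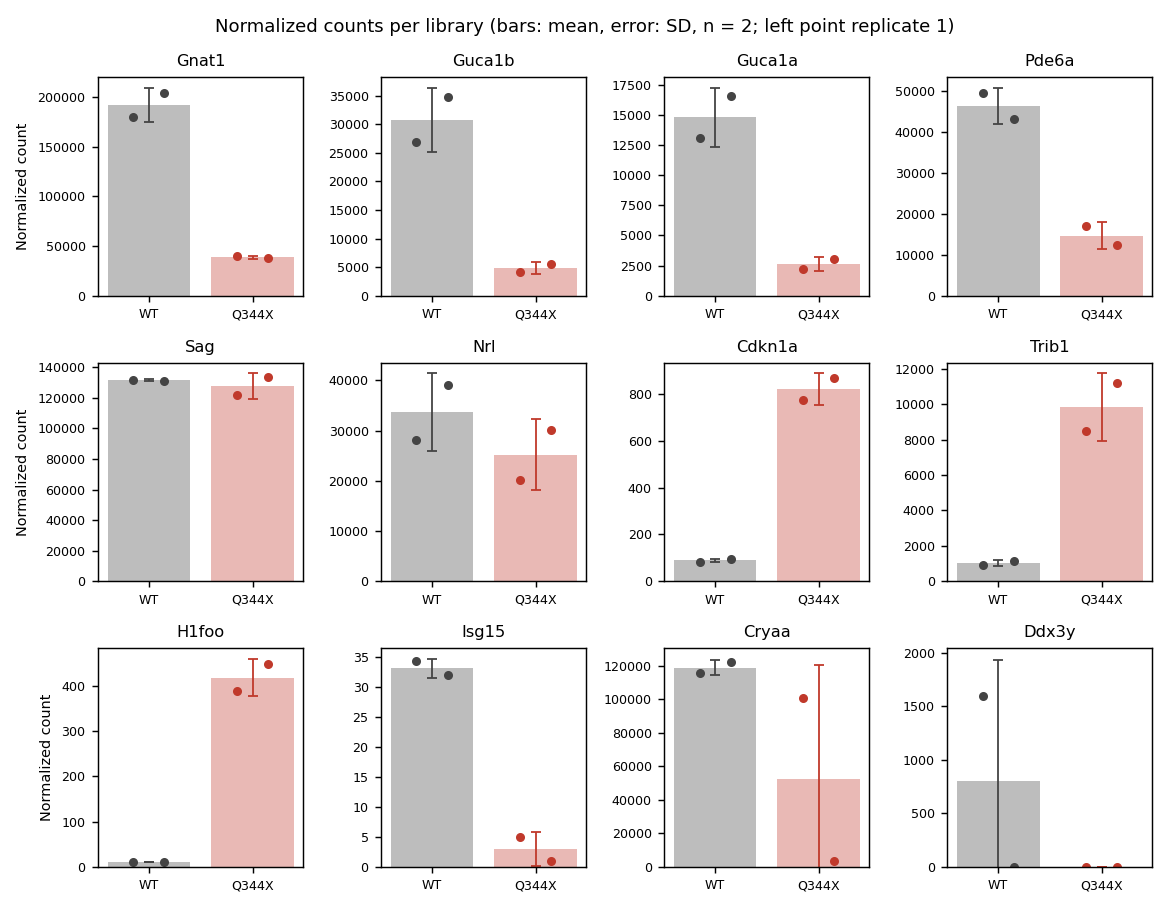
Normalized counts of 12 genes in each library (points; the left point of a group is replicate 1), with group means as bars starting at 0 and the SD over n = 2 libraries as error bars. The Q344X libraries lie below both WT libraries for Gnat1, Guca1b, Guca1a, Pde6a and Isg15 and above them for Cdkn1a, Trib1 and H1foo, while Sag and Nrl overlap. Cryaa is low in Q344X replicate 2 alone (3726) and Ddx3y is at 1598 in WT replicate 1 alone.

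Single genes of the stress, lipid and rhythm lists passed. Of 24 heat shock and proteasome genes Hspa1a (-1.26) fell and 23 did not pass, and adjusted over the list alone 0 passed (limma, camera adjusted p = 0.190). Of 20 antioxidant genes Gpx3 (-2.51 ± 0.23, SE), a secreted glutathione peroxidase, and Sod3 (-1.36 ± 0.24) fell and 18 did not pass, with 2 lower adjusted over the list alone (median 0.03, mean -0.15, camera adjusted p = 0.648, pointing down). Of 18 cholesterol synthesis genes Sc5d (-0.74) fell, 17 did not pass and, adjusted over the list alone, 0 passed (limma, camera adjusted p = 0.408, fry adjusted p = 0.0323). Of 17 circadian clock genes Ciart (1.35) and Cry2 (0.78) rose and 15 did not pass, with 3 higher adjusted over the list alone (camera adjusted p = 0.155, fry adjusted p = 0.0323). Of 17 tested immediate early genes Egr1 (1.44 ± 0.24) rose, Npas4 (-1.83 ± 0.39) and Fosl2 (-1.02 ± 0.24) fell and 14 did not pass, with 1 higher and 3 lower adjusted over the list alone (median -0.49, camera adjusted p = 0.102, or 0.0104 without Q344X replicate 2 and 0.0215 with the length and GC correction). Without 1 of the WT libraries calls were lost for Hspa1a (adjusted p = 0.0957), Sod3 (0.0805), Sc5d (0.312), Ciart (0.0603), Cry2 (0.300), Npas4 (0.109) and Fosl2 (0.259), for Sc5d, Cry2 and Fosl2 without either of them.

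Markers of tissues next to the retina differed between libraries. Lens crystallins, some of which the retina also expresses, were far lower in Q344X replicate 2 than in the other 3 libraries: Cryaa was at 115632 and 122014 in WT and at 100435 and 3726 in Q344X replicates 1 and 2. Of 22 tested lens genes 0 passed in limma, also adjusted over the list alone (median -1.81, camera adjusted p = 0.0271, and adjusted p = 0.711 with an estimated correlation, fry adjusted p = 0.553). Without Q344X replicate 2 the median was 0.36, with 12 members above 0 and 10 below, and camera pointed up. Without Q344X replicate 1 all 22 fell, with a median of -4.45, and 13 fell without WT replicate 1 and 3 without WT replicate 2. Of 16 tested pigment epithelium and melanocyte genes Pmel (1.53 ± 0.23, SE), Rpe65 (1.19 ± 0.20) and Tyr (1.04 ± 0.24) rose, Mitf (-0.92 ± 0.21) fell and 12 did not pass. Adjusted over the list alone, 5 rose and 1 fell (median 0.36, camera adjusted p = 0.0827). Tyr and Mitf lost their calls without WT replicate 1 (adjusted p = 0.199 and 0.259) or 2 (0.106 and 0.171), Tyr without Q344X replicate 2 (0.0696) and Rpe65 without WT replicate 2 (0.0697).

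Red blood cell genes were lower in Q344X, with Hbb-bt (-2.81 ± 0.52, SE) and Hba-a1 (-1.72 ± 0.33) falling among 5 tested and 5 lower adjusted over the list alone (median -1.69, camera adjusted p = 0.00657, or 0.0614 without Q344X replicate 1, and adjusted p = 0.584 with an estimated correlation, fry adjusted p = 0.0503). These globin genes have near-identical copies, and Hba-a1 had adjusted p = 0.0626 without WT replicate 1. Of 12 tested fibroblast, cornea and ciliary body genes Aldh3a1 (-2.28 ± 0.36), a corneal enzyme, and Mfap4 (-1.05 ± 0.22) fell and 10 did not pass. Adjusted over the list alone, 2 were lower (median -0.68, fry adjusted p = 0.0323, camera adjusted p = 0.0206, and adjusted p = 0.584 with an estimated correlation). This list did not pass under quantile normalization (adjusted p = 0.0524), with a minimum mean of 50 (0.154) or without Q344X replicate 1 (0.108), and Mfap4 did not without WT replicate 1 (0.213) or 2 (0.0513). Of 17 blood vessel genes Egfl7 (1.27) and Tie1, both endothelial, rose and 15 did not pass, with 3 higher adjusted over the list alone (median -0.08, mean 0.16, camera adjusted p = 0.359, pointing up). Egfl7 had adjusted p = 0.0692 without WT replicate 1 and Tie1 0.0711 without WT replicate 2. Of 7 tested oligodendrocyte and optic nerve genes Pax2 (2.08) rose, Mobp (-2.68) fell and 5 did not pass, with 1 higher and 2 lower adjusted over the list alone (median 0.07, mean -0.15, camera adjusted p = 0.890, pointing up). Pax2 lost its call without WT replicate 2 or Q344X replicate 2, with log2 fold changes of 1.80 and 1.85 there. Mobp did not pass under 75th percentile scaling (limma adjusted p = 0.0559), under quantile normalization (0.0576), with a pseudocount of 0.5 (0.0518) or with a minimum mean of 50 (0.0607). Of 3 tested skeletal muscle genes Atp2a1 (2.33) rose, Mylpf (-1.44) fell and Acta1 had 0.71, with 1 higher and 1 lower adjusted over the list alone. Mylpf had adjusted p = 0.140 without WT replicate 1, and without WT replicate 2 Mylpf had 0.0835 and Atp2a1 0.0625.

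Sex-linked transcripts differed within the WT group. Eif2s3y, Ddx3y and Kdm5d, encoded on the Y chromosome, were at 2020, 1598 and 852 normalized counts in WT replicate 1 and at 1, 0 and 0 in WT replicate 2, and all 3 were at 0 in both Q344X libraries. Xist, transcribed from the inactive X chromosome, was at 20823 and 37957 in WT replicates 1 and 2 and at 55578 and 26839 in Q344X replicates 1 and 2. WT replicate 1 thus held both Y-linked transcripts and Xist, which a normal male or female mouse does not express together, so this library cannot be taken as RNA of 1 animal. Of the 6 sex chromosome genes in the list, 0 passed in limma, also adjusted over the list alone (camera adjusted p = 0.353, or 4.43e-08 without WT replicate 2, where 4 were lower).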

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

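All 2450 genes past the threshold kept their direction in every alternative in which they were tested. Because the genotypes did not overlap in any of them, most alternatives could not change a direction. Only the other scalings and the length and GC correction could, so the kept directions say little about robustness. With every gene above 0 tested, 153 genes were higher and 383 lower; 30816 genes were then tested, against 16833. Leaving out 1 library, which leaves a lone sample assumed to vary like the other group, gave 555 to 2388 higher and 904 to 3045 lower genes and 9 to 13 lists past the camera threshold; the cause was not tested. The length and GC correction, chosen after seeing the data, gave 1766 higher genes, and the cause was not tested. With an estimated correlation, limma's camera called 0 lists, with 1 list (interferon response, p = 0.0377) at an unadjusted p under 0.05, against 12 lists at the preset correlation and 9 with fry; between-gene correlations estimated from 2 residual degrees of freedom are imprecise. The lens list pointed up without Q344X replicate 2 (adjusted p = 0.00465) and down in the other fits, with adjusted p over the fits without 1 library from 3.97e-37 to 0.00465. Of the 118 called genes that the naming rule picked, 35 did not pass without WT replicate 1, 37 without WT replicate 2, 7 without Q344X replicate 2, 13 under quantile normalization and 76 with no filter. Further calls were lost in fits of all 4 libraries. Slc6a9 and Pdia6 did not pass under 75th percentile scaling (limma adjusted p = 0.0538 and 0.0536) or with a minimum mean of 50 (0.0508 and 0.0501). Selenos did not with that minimum (0.0520) or under quantile normalization (0.0504), nor did Atf3 under the latter (0.0593). Bid did not with that minimum (0.0546) or robust moderation (0.0508), and Bax did not with the length and GC correction (0.0505). The planned edgeR and DESeq2 tests were not run, because in WT replicate 2 and Q344X replicate 1 the worth of 1 read lies so close to 1 that the recovered reads did not pass a check of their unit, and scaling to the 75th percentile took the place of TMM factors. No paired analysis was made, because the labels number no replicates and the numbers used here follow the order of the samples. The second principal component had scores of -17.5 and 27.4 in WT replicates 1 and 2 and of -42.1 and 32.2 in Q344X replicates 1 and 2, a shared direction whose cause was not tested. Genes with a mean under 10 were not tested in the main comparison, and at 18452679 to 19706573 reads in genes their values are the least precise.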

Other observations

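Of the tests below, those on scaling, on length and GC content and on other splits had predictions written before their results were seen. The length and GC correction itself was added after the data were seen, and the other tests were chosen afterwards. Among 19 tested genes of the histone clusters, a class chosen after its values were seen, 13 were lower in Q344X, 0 were higher and 6 did not pass in limma, with a median log2 fold change of -2.77. Hist1h1c, a linker histone gene, was the most abundant of these and had a log2 fold change of -2.67 ± 0.25 (SE), and Hist1h4i had -3.40 ± 0.26. Most histone genes make transcripts without a poly-A tail, and their near-identical copies can share reads. Long noncoding classes (antisense, lincRNA, processed transcript and bidirectional promoter genes, chosen after their values were seen) had 64 higher and 269 lower genes, 80.8% of their calls lower. Of the calls among protein-coding genes 58.7% were lower, and the shares were 73.8% in TEC genes (transcripts to be experimentally tested), 60% in sense intronic genes and 52.5% in processed pseudogenes. Because the classes were picked for their values, this difference was not tested.

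The fall of rod phototransduction genes was set against 2 technical or compositional explanations. Fewer rods as the only change would lower the rod isoforms that have a cone counterpart of their own alike. Yet of 9 such genes (Gnat1, Gngt1, Pde6a, Pde6b, Pde6g, Cnga1, Cngb1, Sag and Slc24a1, chosen after their values were seen) 5 had a 95% interval that left out their median of -0.91. Sag and Cnga1 lay above it and Gnat1, Pde6a and Slc24a1 below it. The intervals were not adjusted for 9 comparisons, and the median came from the same genes. These values describe an uneven fall and are no independent test. The list median was -1.12 in the main fit, -1.09 under 75th percentile scaling and -1.02 under quantile normalization. The choice among these scalings thus does not account for the fall. Size factors of 0.962 to 1.04 left little room for it, and a change in total RNA cannot be seen under any of these scalings. A hypothesis that remains open is a selective loss of some rod transcripts in surviving rods, possibly with part of the rods lost. Counts of rods in sections and transcript levels per rod would separate it from an unequal loss of cells that differ in these transcripts, and neither was analysed here.

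Higher ribosomal protein transcripts were set against 2 technical explanations. Genes with a short union of annotated exons were slightly higher in Q344X (median log2 fold change 0.19 in the shortest sixth of protein-coding genes and -0.11 in the longest). After correction for this length and for GC content the list median was 0.88, against 0.84 before. The values argue only against a trend in these annotated measures as the whole cause. Annotated exons can exceed the expressed mRNA, so a bias by the length of the mRNA itself was not tested. The SE of the corrected median, 0.10, is taken over the 20 genes, which move together, and does not measure the spread between libraries. The list median also differed by 0.67 between the Q344X libraries, less than the 0.84 between genotypes and more than a small share of it, so variation between animals or RNA preparations of one genotype may account for part of the shift and cannot be told apart from an effect of genotype with 2 libraries per group.

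The 4 libraries can be split into pairs in only 3 ways, too few for a share under 0.05. The real grouping gave 2450 genes past the threshold and was the 1 split with as many, and the highest of the others gave 0 in limma, with 504 and 8 genes at an unadjusted p under 0.05 in the other splits against 5833. The first principal component, with 74.8% of the variance, separated the genotypes, so the other splits count that difference as spread within groups. Few calls were thus fixed in advance for them, and the comparison cannot tell genotype from any other difference between the pairs.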
